A study of Rattus norvegicus with 7 samples.

How the data were processed

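The samples were vomeronasal epithelia of 7 male LEW/Crl rats aged 8 weeks, 1 library per rat, all in one group taken from the tissue label. Per the labels' protocols, animals were flushed of blood with heparin before dissection, polyA-selected RNA was made into libraries with a TruSeq kit, and stranded single-end reads of 100 nucleotides were sequenced on a HiSeq2500. PolyA selection means that transcripts without a polyA tail were not measured.

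Reads were aligned with STAR 2.7.1a and counted with featureCounts 1.6.5, per the submitters' processing notes, whereas the file headers name featureCounts 1.6.3. Per the file headers, the deposited values are estimated counts per gene model: a read was counted on exons of a gene on the matching strand (strand setting 2), with an overlap of at least 1 base and no minimum mapping quality (0), and a read mapped to several places was counted at each as a fraction. The values are not scaled for depth or length. Receptor families hold near-identical copies, so that a fractional count can credit a silent copy with reads of an expressed one and take them from the latter. Models whose counts were whole in every rat were therefore also analysed alone. The length column of the deposited files gives each model's exon bases, per the file headers.

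The annotation was Ensembl release 67 on RGSC3.4, extended by the authors, per the file headers. Of 29630 models, 29516 carried Ensembl identifiers and 114 names given by the authors. All coordinates are those of the files. The gene table used for names (47357 genes) had an Ensembl identifier for 0 of them, so that 0 identifiers could be matched to a symbol. Comparisons fixed for V2R and formyl peptide receptor genes, the lists of cell type markers and the correlations of receptor families with markers of neuron layers need symbols and were not run. V1R models were taken from the authors' block of 224 models that stands ahead of the genome-ordered rest of the annotation. Its 115 pseudogenes are 109 named as such, 1 of which stood among the intact models, and 6 with an Ensembl identifier only. Its 109 intact models are 5 named and 104 with an Ensembl identifier only, which the files do not name as V1R, so that their class and that of the 6 pseudogenes are inferred from the layout. All 109 had 1 exon, 861 to 1068 bases and a length divisible by 3, that is, coding length without UTRs, against 50 of 115 pseudogenes with a length divisible by 3 and 41 to 1145 bases.

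CPM and RPKM were computed here from the deposited counts, each rat's total and the model length. A model was detected with at least 10 counts in at least 4 of 7 rats. Levels were compared as log2(mean RPKM + 0.1), a scale that understates differences of low models. Near meant an edge-to-edge distance of at most 500 kb from an intact V1R gene on the same chromosome. Shares detected were compared by Fisher's exact test and levels by a permutation test over genes with 100000 resamples, or an exact permutation test (values rounded to 0.001) where a class had fewer than 10 models, all two-sided, at a threshold of 0.05. Intervals of shares detected are exact (Clopper-Pearson) at 95%, and those of a rat's share of counts are 95% Wilson score intervals on rounded counts. With 64085829 to 74924005 counts per rat, 1 CPM stands for 64.1 to 74.9 counts. A count of 0 allows 3 counts, that is 0.0400 to 0.0468 CPM in a single rat and 0.00622 CPM over the group. The 21 pairs of libraries differed by 12.8 to 117.5 times their degrees of freedom in chi-square, so that each was kept as a library of its own.

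Variability between rats was the square root of the tagwise dispersion from edgeR 4.0.16 (R 4.3.3), with an intercept-only model and TMM factors on counts rounded to whole numbers, for 16670 detected models. The median of each class was set against 10000 random lists of the same size, each member drawn from the 200 models nearest in mean expression, and ranges of lists run from the 2.5 to the 97.5 percentile. DESeq2 1.42.0 size factors were an alternative. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did the rest, and matplotlib 3.10.9 drew the figures.

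The steps were tested on simulated data. For the variability test, counts were drawn for 16670 models whose dispersions varied, with 4 times the dispersion in 200 of them. A list of 102 of these was called at a permutation p = 0.0002, with a median of 1.52 times that of matched lists where 2 times was simulated. Tagwise values are drawn towards the trend, which may account for the shortfall, but this was not tested. Of 200 unchanged lists, 11 were called. For the near and far comparison of 115 models, 8 of 200 simulations without a difference and 200 of 200 with a log2 difference of 3 were called. These simulated levels were normal with an equal spread in both groups. Many real ones lie at the floor (0 counts in 48 of 95 near and 18 of 20 far models), with SDs of 1.46 and 0.311. The simulation therefore does not give the error rate or power for the observed difference of 0.72.

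The text names, by a rule fixed before the data were examined, the most abundant models, the highest intact V1R genes, the highest near and far pseudogenes, intact genes alone and the models that varied most. Identifiers without a gene name are printed sparingly, and most such models are given by position. Named pseudogenes and intact genes below those ranks, and the models on chromosome 7, were chosen after their values were seen. Alternatives fixed in advance were other count minimums, pseudocounts, scalings and distances, whole counts only, 1 value per locus and leaving out each rat in turn.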

Results

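RNA was sequenced from the vomeronasal epithelium of 7 male rats of the inbred Lewis strain (LEW/Crl), each 8 weeks old and each giving 1 library. The vomeronasal organ is a chemosensory structure of the nasal cavity whose sensory neurons express receptors of the type 1 (V1R) and type 2 (V2R) vomeronasal families. All rats belonged to one group, so that the comparisons were made between classes of genes within the same animals, and the 7 rats gave the spread of each value. The libraries held 64085829 to 74924005 counts assigned to gene models. Between 20451 and 20824 of the 29630 models had a count in a rat, and 16670 models reached 10 counts in at least 4 of the 7 rats, which is called detected here. Pairwise correlations of log2(CPM + 1) between rats lay between 0.985 and 0.998, and no pair of libraries agreed within counting noise. Reads of the single-cell experiment that the study design mentions were not analysed here.

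The share of counts assigned to V1R models was measured first. The intact models hold coding length without UTRs, so that any reads from their UTRs are left out of this share. The 109 intact V1R genes together took 0.0519% ± 0.00877 of all counts (SD, n = 7), and the 115 V1R pseudogenes took 0.00257% ± 0.000406 (SD, n = 7). Pseudogenes, copies of receptor genes that have lost an intact coding sequence, thus were credited with 4.74% ± 0.184 of the V1R counts (SD, n = 7). On average only 467 of their 1783 counts per rat came from models without shared reads, so that their own contribution is uncertain. The intact share was lowest in rat 6, at 0.0383%, and highest in rat 7, at 0.0639%, a 1.67-fold range. Wilson score 95% intervals of these single-rat shares were 0.0379% to 0.0388% and 0.0633% to 0.0645%. These intervals and the detection limits cover counting error only, not the spread between rats. The reads carried no molecular identifiers, so that counting error itself may be understated. Intervals of shares detected, given below, instead treat models as independent draws. These shares depend on a few very abundant models: without the 10 most abundant ones in the library total, the intact share was 0.0950% ± 0.0129 (SD, n = 7).

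**Figure D1:**
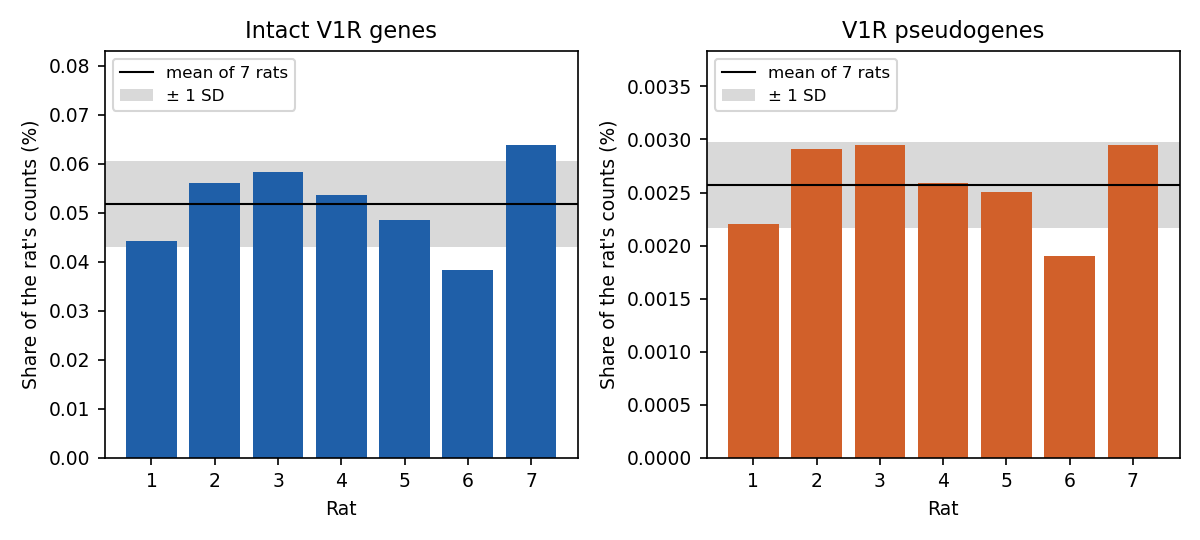
Share of each rat's counts (%) in the 109 intact V1R genes (left) and in the 115 V1R pseudogenes (right), 1 bar per rat, with the mean of the 7 rats as a line and ± 1 SD as a grey band. The intact share runs from 0.0383% in rat 6 to 0.0639% in rat 7, and rat 6 is also lowest for pseudogenes.

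Intact V1R genes were broadly expressed in the tissue and pseudogenes mostly were not. Of the 109 intact genes 102 were detected (93.6%, exact binomial 95% interval 87.2% to 97.4%), against 16 of the 115 pseudogenes (13.9%, 8.17% to 21.6%). The intact genes had a median of 2.88 CPM, with the middle of their distribution between 0.834 and 6.94 CPM at its quartiles. The highest was ENSRNOG00000033061 on chromosome 1 (73409743–73410699, RGSC3.4), at 37.8 ± 6.60 CPM (SD, n = 7), which was 7.29% of the summed CPM of intact genes. The next was ENSRNOG00000029625 on chromosome 1 (64752662–64753594) at 21.3 ± 4.23 CPM, followed by a gene on chromosome 4 (124161190–124162170) at 18.2 ± 3.51 CPM and one on chromosome 1 (57224972–57225868) at 17.9 ± 3.18 CPM (SD, n = 7 each). The 10 highest genes made up 34.5% of the intact V1R signal, and 18 genes made up 50%. All 5 intact genes that the authors named were detected, NG_Vom1r16 at 9.51 ± 1.83 CPM, NG_Vom1r13 at 2.85 ± 0.488, NG_Vom1r4x2 at 2.09 ± 0.425, NG_Vom1r55 at 0.834 ± 0.192 and NG_Vom1r44l at 0.488 ± 0.0662 (SD, n = 7). The 7 intact genes that were not detected included 1 on chromosome 4 (86172617–86173516) with no count in any rat, which allows up to 0.00622 CPM over the group, and 3 neighbours at one end of a chromosome 1 cluster (56587323 to 56731967).

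Among pseudogenes, 66 of 115 had no count in any rat. The highest was ENSRNOG00000032125 on chromosome 1 (73551908–73552740) at 5.52 ± 0.836 CPM, and NG_Vom1rn-ps63 on chromosome 1 (72448782–72449735) followed at 4.60 ± 0.855 CPM. NG_Vom1rn-ps64 (chromosome 1, 73502065–73502840) had 2.76 ± 0.571 CPM and a pseudogene without a name on chromosome 4 (86064767–86065726) had 2.68 ± 0.336 CPM (SD, n = 7 each). NG_Vom1rn-ps64 and ENSRNOG00000032125 lie inside the span of another model on the opposite strand, and the counting used strand. Only 6 of the 16 detected pseudogenes had whole counts in every rat, among them NG_Vom1rn-ps84 at 1.14 ± 0.286 CPM, NG_Vom1rn-ps6 at 0.884 ± 0.337 and NG_Vom1rn-ps17 at 0.793 ± 0.0962 (SD, n = 7). The other 10, including ENSRNOG00000032125, NG_Vom1rn-ps63 and NG_Vom1rn-ps64, held fractions of reads that also mapped elsewhere, so that their levels are uncertain. The same holds for 68 of the 102 detected intact genes, ENSRNOG00000033061 included.

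The difference in the share detected was 79.7 percentage points (Fisher's exact test, two-sided, p = 4.54e-37). Mean log2(RPKM + 0.1) was 1.43 for intact genes and -2.66 for pseudogenes, a difference of 4.09 (SE 0.22), with p = 1e-05 in a two-sided permutation test over genes, the smallest that 100000 resamples can give, and the same direction in 7 of 7 rats. Across the 6 tests of the 3 comparisons between classes of V1R models, the Benjamini-Hochberg adjusted values of these tests were 2.73e-36 and 3e-05. Genes are not independent replicates, and the 104 intact genes and 6 pseudogenes without a name, 3 of the latter detected and ENSRNOG00000032125 among them, were assigned to their class by their place in the authors' annotation.

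**Figure D2:**
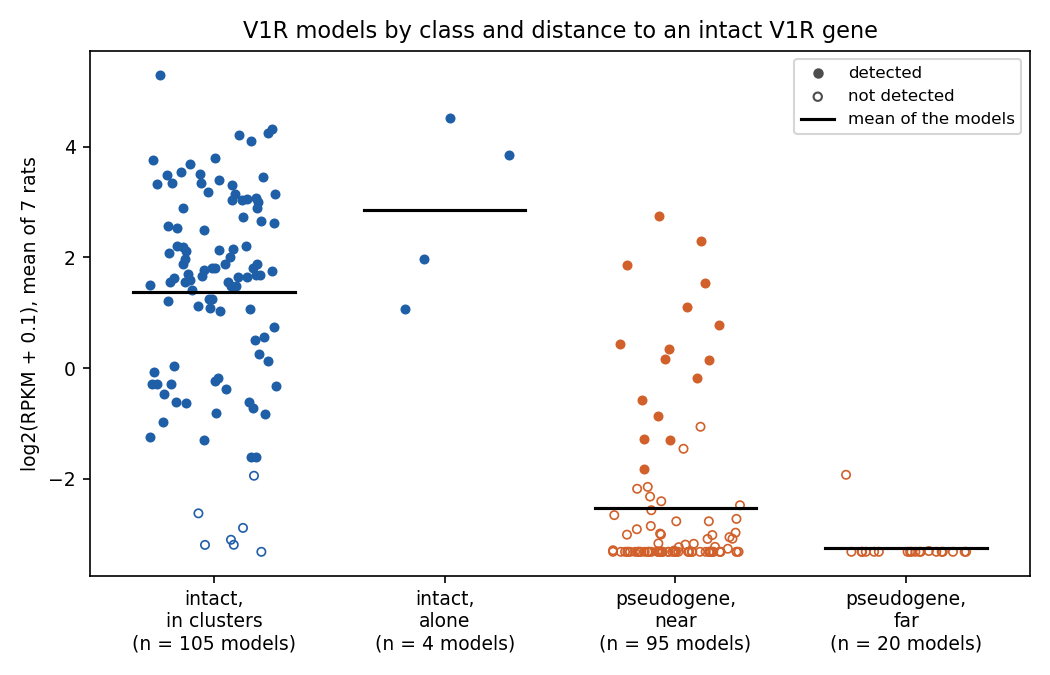
Level of each V1R model as log2(RPKM + 0.1), mean of 7 rats, for intact genes in clusters, intact genes alone, pseudogenes near an intact gene and pseudogenes far from one. Each point is 1 model, filled where detected and open where not, and black lines are means over models. No pseudogene of the far class is detected, and most models of that class sit at the floor of 0 counts.

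Whether a pseudogene's transcription goes with its place among intact receptor genes is a question of the study. The 16 detected pseudogenes all lay within 500 kb of an intact V1R gene, 12 of them on chromosome 1 and 4 on chromosome 4, at 8.63 to 83.0 kb from the nearest one (median 33.8 kb). Of the 95 pseudogenes that near, 16.8% were detected (exact binomial 95% interval 9.94% to 25.9%). Of the 20 pseudogenes farther away, none was detected (upper limit 16.8%), and 18 had no count in any rat. The 2 others were NG_Vom1rn-ps94 on chromosome 4 (146000779–146000968), at 0.0309 ± 0.0133 CPM, and NG_Vom1rn-ps96 on chromosome 7 (14987513–14988487), at 0.000956 ± 0.00253 CPM (SD, n = 7), both with fractions of shared reads. The far pseudogenes include 7 on chromosomes without an intact V1R gene in the annotation, such as NG_Vom1rn-ps115 on chromosome 14 and NG_Vom1rn-ps95 on chromosome 5, and 5 that lie between 500 kb and 1 Mb from one. On chromosome 7, none of 17 pseudogenes was detected, 13 of them near the 3 intact genes there, which were all detected. Several of these 13 were shorter than the shortest detected pseudogene, which had 551 bases, and length was not held equal here.

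The difference of 16.8 percentage points in the share detected did not pass the test (Fisher's exact test, two-sided, p = 0.0702, adjusted over the 6 tests 0.105). Mean log2(RPKM + 0.1) was -2.53 for near and -3.25 for far pseudogenes, a difference of 0.72 (SE 0.16) on that scale with p = 0.0265 in a two-sided permutation test over genes, in the same direction in 7 of 7 rats, and with an adjusted value of 0.053. The far models were shorter (median 295.5 against 822 bases). With models of at least 600 bases only, 15 of 67 near and 0 of 9 far ones were detected (Fisher's exact p = 0.191). With whole counts in every rat only, 6 of 73 and 0 of 18 were (Fisher's exact p = 0.594), but models with 0 counts always pass that filter (48 of the 73 and 18 of the 18), so that this says nothing about shared reads. With near set at 100 kb, 16 of 85 near and 0 of 30 far pseudogenes were detected (Fisher's exact p = 0.011). At 1 Mb, 16 of 100 near and 0 of 15 far ones were (Fisher's exact p = 0.125).

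**Figure D3:**
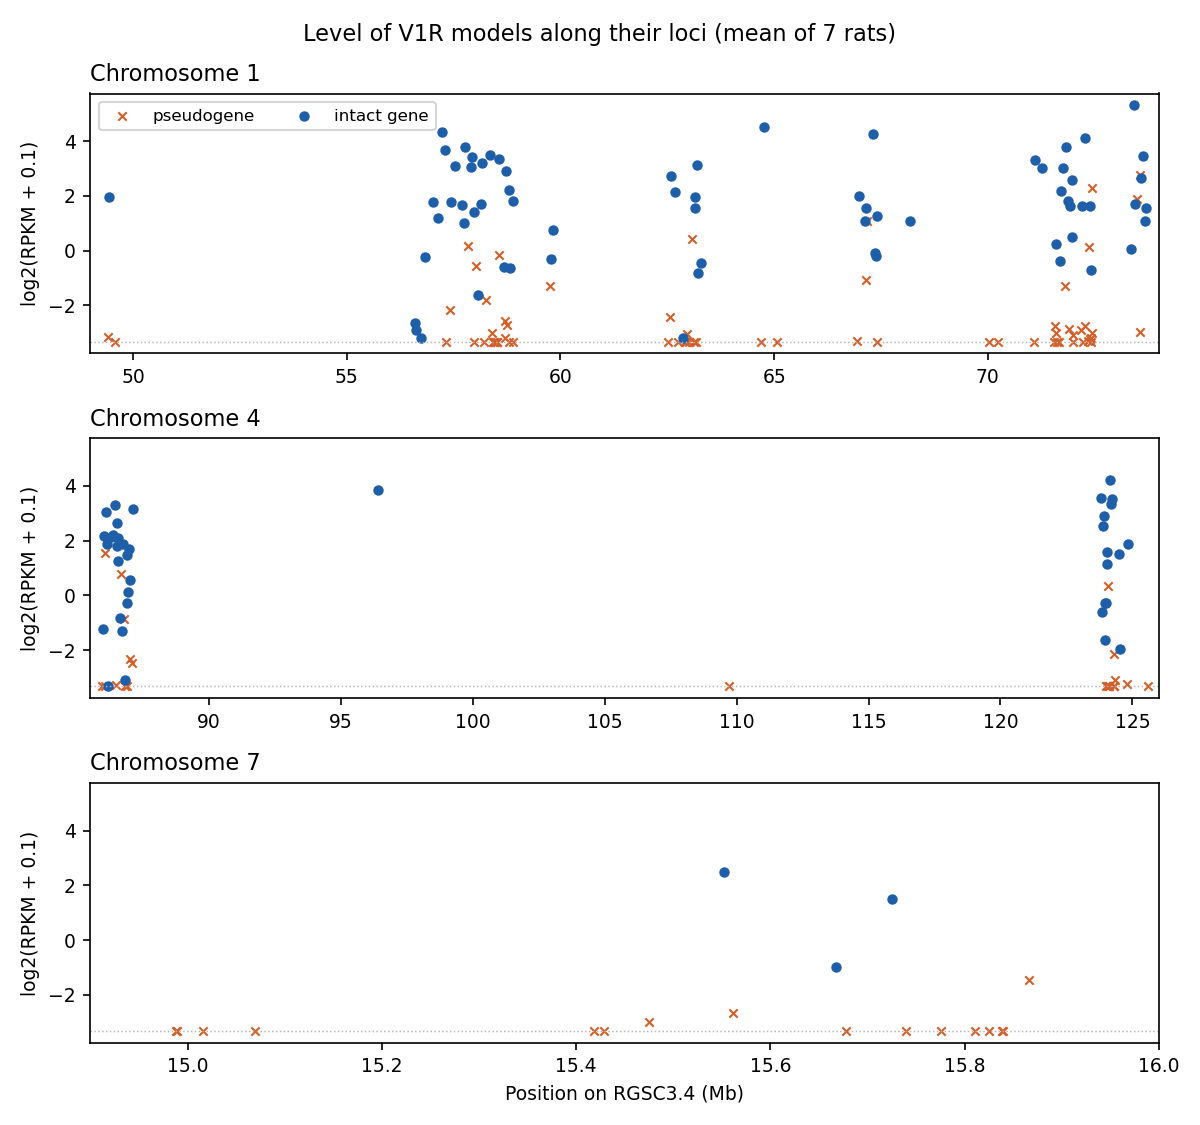
Level of V1R models, log2(RPKM + 0.1), mean of 7 rats, against position in Mb on RGSC3.4 for chromosomes 1, 4 and 7, with intact genes as dots, pseudogenes as crosses and the floor of 0 counts as a dotted line. Detected pseudogenes stand among intact genes on chromosomes 1 and 4, and the intact gene of chromosome 4 at 96415882 has no other V1R model beside it.

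Intact V1R genes that stood apart from the clusters were also compared with those inside them. Only 4 intact genes had no other intact V1R gene within 500 kb, and all 4 were detected, against 98 of the 105 others (93.3%). ENSRNOG00000029625, on chromosome 1 at 64752662–64753594 and 1470 kb from the nearest other intact gene, was the second highest of all intact genes, at 21.3 ± 4.23 CPM. ENSRNOG00000030085 on chromosome 4 (96415882–96416799), 9.32 Mb from the nearest, had 13.2 ± 2.08 CPM (SD, n = 7). The counts of both were whole in every rat. The remaining pair, both on chromosome 1, had 3.44 ± 0.771 CPM at 49437215–49438111 and 1.83 ± 0.425 CPM at 68176590–68177507 (SD, n = 7 each). The counts of the latter equalled those of a clustered gene at 67115748–67116665 in every rat, so that its reads cannot be told from those of that copy and its detection cannot be credited to it. Without this pair of models, 3 of 3 genes alone and 97 of 104 others were detected, and the level differed by 2.07 (exact permutation p = 0.060). The difference in the share detected did not pass the test (Fisher's exact p = 1, adjusted 1), and the mean log2(RPKM + 0.1) of 2.85 against 1.37 gave a difference of 1.48 (SE 0.82) with a two-sided exact permutation p = 0.124 and an adjusted value of 0.148. With alone set at 100 kb the difference in the share detected turned to -7.12 percentage points (14 of 16 against 88 of 93, Fisher's exact p = 0.273). With whole counts in every rat only, 2 genes alone, ENSRNOG00000029625 and ENSRNOG00000030085, stood against 37 others, and the level differed by 3.51 (SE 0.45, exact permutation p = 0.0148), although fewer than 3 genes alone had been set in advance as too few for a test.

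V1R genes were also examined for how much they varied between these inbred animals. The rank order of intact genes was nearly the same in every rat, with Spearman's rho between 0.983 and 0.992 across the 109 genes. The median biological coefficient of variation of the 102 detected intact genes was 16.4%, against 13.9% for random lists matched on mean expression (central 95% of 10000 lists 12.9% to 15.1%, two-sided permutation p over lists 0.0004, adjusted 0.0008 over both classes). The 16 detected pseudogenes had 20.2% against 18.1% for their matched lists (permutation p = 0.316, adjusted 0.316). The random lists hold genes drawn singly, whereas V1R genes moved together (relative to the rat's other intact V1R genes their median coefficient of variation fell from 19.2% to 8.78%), so that the p-value of the intact genes is too small. Without rat 6, whose mean r with the others was 0.991 and lower than that of all but rat 1, the median of the intact genes was 13.9% against 13.4%, and the call ended (permutation p = 0.338). It also ended with genes of whole counts only (17.4% against 16.1%, 34 genes, permutation p = 0.218).

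The most abundant transcripts of the tissue came from a short stretch of chromosome 3. Of the 10 most abundant models 6 lay between 3858161 and 5432041, and they held 38.2% ± 2.41 of all counts (SD, n = 7). The highest, ENSRNOG00000027963 at 3934278–3937462, took 17.0% ± 1.06, and ENSRNOG00000042407 at 3858161–3861440 took 14.0% ± 0.824 (SD, n = 7). The other 4 models of the 10 were on chromosome 1 (190427623–190564079) with 4.59% ± 0.299, on chromosome 4 (165561239–165603598) with 1.29% ± 0.146, and a pair on the mitochondrial genome with 0.783% ± 0.111 and 0.666% ± 0.050 (SD, n = 7). The mitochondrial genome held 2.07% ± 0.222 of the counts (SD, n = 7). The files do not pair these identifiers with gene names, so none is given.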

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

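Of 45 values tested for a rat far from the other 6, 1 stood apart: the share of counts in the most abundant model, ENSRNOG00000027963, was 14.7% in rat 7 and 16.7% to 17.7% in the other rats, with the gap to the nearest rat at 0.672 of the whole range (Dixon's test at its 95% critical value). Chance flags about 1 in 20 such values, which is more than were seen.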

How the results depend on the processing

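Models named by the authors only, models of at least 600 bases, leaving out pseudogenes with an Ensembl identifier only, leaving out models of equal counts, differences paired within rats and division by V1R counts were chosen after seeing the data. Intact genes exceeded pseudogenes under every alternative run, by 68.4 to 88.1 percentage points detected and by 1.88 to 6.33 in log2 level. The near and far difference in level, 0.72 (adjusted permutation p = 0.053), stayed between 0.71 and 0.73 with each rat left out. Unadjusted, it stayed past the threshold. It lost the call with a pseudocount of 1 (0.22, p = 0.0599), whole counts only (0.42, p = 0.0503, a filter that 0 counts always pass), near within 1 Mb (0.66, p = 0.0718), models named by the authors only (5 intact genes, 0.35, p = 0.155) and models of at least 600 bases (0.94, exact permutation p = 0.0576). The last had 9 far models. Distance to the 5 intact genes moved the classes to 34 near and 75 far, 6 of the latter detected. The cause of the other losses was not tested. The difference in the share detected passed the threshold with a minimum of 3 counts (23.2 percentage points, Fisher's exact p = 0.0123), near within 100 kb (18.8, p = 0.011) and 1 value per locus (72.7, p = 5.31e-05), where a locus with more pseudogenes has more chances to hold a detected one. It stayed between 15.8 and 16.8 with each rat left out. Intact genes alone against clustered ones reversed in share detected with 100 kb (-7.12 percentage points, Fisher's exact p = 0.273), and the level difference passed the threshold over genes with whole counts only (3.51, 2 alone against 37, exact permutation p = 0.0148) and in no other alternative over genes (0.47 to 2.08). The intact V1R share moved to 0.0950% without the 10 most abundant models, and the pseudogene share to 0.00472% there and to 0.00326% on counts divided by length. The cause was the smaller total or the division itself. The variability of intact genes, 1.18 times that of matched lists, lay at 1.04 to 1.32 with each rat left out; it was 1.04 without rat 6 (permutation p = 0.338) and 1.08 with whole counts only (p = 0.218, 34 genes). On the CV of CPM the ratio was 1.43. It reversed to 0.653 after division by the rat's summed other intact V1R counts, with the matched lists undivided. For pseudogenes the ratio of 1.12 lay at 0.986 to 1.17 with each rat left out, reversed to 0.986 without rat 6 and to 0.915 with whole counts only, neither past the threshold. Of 127 alternative values with a test, 110 kept direction and side of the threshold, 8 lost and 5 gained the call and 4 reversed; of 18 without a test, 15 moved by less than 1 SD and 3 by more. Paired within rats, the level differences were 4.08 ± 0.18, 0.70 ± 0.05 and, for genes alone, 1.48 ± 0.10 (SD, n = 7), each in the same direction in 7 of 7 rats (exact sign-flip permutation p = 0.0156, the smallest that 7 rats can give). This leaves out the spread between genes, so that it passes for genes alone where the test over genes does not. Alternatives that need a genome (unique 100-mers) or gene symbols were not run. A minimum of 3 counts detected 22 pseudogenes against 16 and 104 intact genes against 102. A lower minimum can only add models, so that this does not show whether depth limits the pseudogenes.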

Other observations

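The tests of shared reads, model length, rat 1, division within matched lists and the relations across rats were chosen after the results were seen. Those of upstream genes and whole regions were chosen before. The prediction for a shared rise or fall was also written before, whereas division by V1R counts as an alternative setting was chosen after.

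V1R genes lay in 13 loci with at least 1 intact gene, and the level of their genes did not differ detectably between loci. The largest, on chromosome 1 (56587323–58889552), held 26 intact genes and 19 pseudogenes and gave 130 ± 22.0 CPM, 25.1% of the intact V1R counts (SD, n = 7). A chromosome 1 locus at 71070539–72449735 with 15 intact genes gave 80.0 ± 13.9 CPM, and one on chromosome 4 (123811714–124819364), also with 15, gave 75.3 ± 12.7 CPM (SD, n = 7). Over the 8 loci with at least 3 intact genes (103 genes), 4.23% of the variance of log2(RPKM + 0.1) lay between loci (permutation p = 0.757). Among the 95 near pseudogenes, the level showed Spearman's rho of -0.17 with the distance to the nearest intact gene (permutation p = 0.101, adjusted over 3 relations 0.152), -0.02 with the level of that gene (p = 0.851, adjusted 0.851) and 0.23 with length (p = 0.0252, adjusted 0.0755), all across genes, which are not independent replicates.

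Across the 7 rats, summed CPM of pseudogenes without shared reads moved with that of intact genes (Pearson's r = 0.890, exact permutation p = 0.00794, adjusted over 4 relations 0.0159; Spearman's rho = 0.75, exact permutation p = 0.0663, adjusted 0.133). Without the 2 rats farthest from the median r was 0.918, and without rat 6 it was 0.78 (exact permutation p = 0.0681). On average 184.7 of the 467 counts per rat in this sum came from the pseudogene without a name on chromosome 4 (86064767–86065726). Its class was inferred from its place in the annotation, and it has 1 exon and 960 bases, within the range of the intact models. The relation without this model was not tested. All pseudogenes together gave r = 0.963 and rho = 1 (exact permutation p = 0.0002 and 0.0004, adjusted 0.00079 and 0.00159, r = 0.966 without those 2 rats), but on average only 467 of their 1783 counts per rat came from models without shared reads. The sum of the 2 most abundant models gave r = -0.714 with intact V1R genes (exact permutation p = 0.0625, adjusted 0.0833; rho = -0.64, p = 0.139, adjusted 0.185), and r = -0.102 without the 2 farthest rats. Mitochondrial counts gave r = 0.070 (exact permutation p = 0.881, adjusted 0.881; rho = 0.071, p = 0.906, adjusted 0.906).

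A pair of models were near 0 in some rats and far higher in others. A model on chromosome X (3011520–3055048, 24 exons) had 33.2 to 35.4 CPM in 5 rats and 1 count each in rats 4 and 6 (0.0148 and 0.0151 CPM). A model on chromosome 1 (237841539–237856579, 9 exons) had 16.3 CPM in rat 5 and 15.9 CPM in rat 6, and 0 to 2 counts in each of the others. These were the only models of 14368 scanned with such a split in at least 2 rats each way.

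The first pattern weighed is that detected pseudogenes lay near intact V1R genes. Reads shared with near-identical copies in RGSC3.4 are argued against as the source of every detected pseudogene. Of the 16, 6 had whole counts in every rat. Reads of a copy absent from RGSC3.4 could also give whole counts, and this was not tested. Transcripts running in from an intact gene within 20 kb upstream are argued against as the source of most detected near pseudogenes. Only 12.5% of them (2 of 16) had such a gene on the same strand, against 13 of 79 of those not detected. Their nearest intact gene in either direction lay at a median of 33.8 kb, so that this window left many out. Transcripts from farther upstream stay open and were not tested. Shared reads as the source of the near and far difference stay open, because the test on whole-count models (Fisher's exact p = 0.594388) is void: models with 0 counts always pass that filter and 10 of the 16 detected ones are removed by it. Also open are shorter far models, since among those of at least 600 bases the difference was not smaller, at 22.4 percentage points and 0.94 in log2 level, but only 9 were far (Fisher's exact p = 0.191075), and transcription of whole regions, since 59.7% of the 243 other models near intact V1R genes and 56.3% of models elsewhere were detected (Fisher's exact p = 0.299). The design names no difference between groups of animals to set against these.

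The second pattern is the variability of V1R genes between rats, which rests on rat 6: without it the ratio to matched lists was 1.04 (permutation p = 0.338). In rat 6, 67 of 11178 models lay at least 2-fold above the median of the other rats, against 79 in rat 1, 36 in rat 5 and 0 to 6 in the rest, and 10 lay as far below, within the 0 to 24 of the others. A shared rise or fall of all V1R genes in a rat is a candidate explanation: after each gene was divided by the rat's summed counts of the other intact V1R genes, the median coefficient of variation fell from 19.2% to 8.78% (0.0878 as a fraction), to 0.458 of its value. Matched random lists divided in the same way by their own members fell to a median of 0.919 of theirs (lowest of 10000 lists 0.722). A different share of sensory neurons in each dissection could give such a shift, but it was not tested, because neuron markers could not be named.

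The third pattern is in rat 1, whose mean r with the other rats was the lowest, at 0.987. In it 61 models on 17 chromosomes, none of them a V1R model, were at least 10-fold above every other rat, against 0 or 1 such models in each other rat, and together they held 0.213% of its counts. The highest, on chromosome 10 (89057240–89061150), had 294 CPM in rat 1 and at most 0.763 CPM elsewhere. A scaling difference of the library is argued against, since its median model lay at -0.0869 in log2 ratio to the other rats. Other tissue in the dissection of rat 1 stays open: 52.46% of the 61 lay within 500 kb of another (32 models, against at most 22.95% in 1000 random lists), for example 5 at 140320625–140655441 on chromosome 7, but without gene names no marker list could be tested.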
